A study of Macaca mulatta with 6 samples.

How the data were processed

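Tracheal tissue of rhesus monkeys was sequenced in 6 libraries, 3 from a control group given normal saline and 3 from a group given a tracheal lubricant coated with Oxy@Lipo/Gel. Groups and replicate numbers were taken from the descriptions in the labels. Per the labels' protocols, RNA was selected for poly(A), libraries were made strand-specific with dUTP, and reads were paired. The aligner, the counting program and the annotation are not given in the sources used here, nor is whether counting used the strand, so a gene and an overlapping antisense gene may share counts. Per the submitters' processing notes, the builds GRCm38 (mouse), rheMac8 and Mmul_8.0.1 were named without a role.

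The deposited count table holds whole-number counts for 28536 genes in each of the 6 libraries. The deposited FPKM table holds, per the file headers, fragments per kilobase of gene length, scaled to the library total. Of the 17796 genes with 5 or more counts in every library, 17796 gave a single whole-number gene length (within 0.01 base) when the count was divided by the FPKM and the column total, so the FPKM values carry the same information as the counts and are no independent measurement. Genes without a count in any library numbered 540. Of 16971 gene symbols 16863 were found in the rhesus reference table, and of 11565 LOC identifiers 0 were, so LOC identifiers stay unnamed. Whether the counts rest on the gene models of this reference or on those of another annotation was not determined. No coordinates were used.

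Library totals ran from 17097177 to 23405294 counts. A count of 3 corresponds to 0.128 to 0.175 CPM per library, and intervals and floors cover counting error only. No pair of replicates was alike within sampling noise: chi-square per degree of freedom was 49.95 or more for every pair.

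Groups were compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with TMM normalization, a filter with a count of at least 10 in enough libraries and a total of at least 15 (filterByExpr), group as the only term, and Benjamini-Hochberg adjustment at 0.05. This left 18676 genes. The SE of a log2 fold change is its size divided by the square root of F. CPM values use the TMM library sizes.

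Before the data were examined, 47 gene lists were fixed for responses to injury, stress, pain and barrier function and for cell types that a piece of airway wall can hold. Lists with 5 or more tested members, 43 of them, were tested with camera (limma 3.58.1) with a preset correlation of 0.01, beside camera with a correlation estimated from each list, and fry. The lists of MHC class II antigen presentation (3 members tested) and erythroid cells (4) were too short to test, and the lists of mitochondrially encoded and sex-linked genes were not analysed here. Counts within a list were given over all genes and adjusted over the list alone. Per-library list means are means of log2 CPM, relative to the mean of all 6 libraries.

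The genes named were fixed by rule before the data were examined. Of called genes with non-overlapping groups and a mean of at least 1 log2 CPM, the 12 with the largest log2 fold change in each direction were named. For at most 10 lists with the smallest camera p, the 4 members with the smallest p were named, and for other lists the member with the smallest p. SCN9A, SCN10A, TRPV1, PTGS2, IL1B, IL6, TNF, CXCL8, CALCA and TAC1 were always named. LOC identifiers were left out of the first rule after they were seen among the largest changes (11 of the 24 would have been such identifiers). CD79A, CD79B, NPAS2, PER2, PER3, NR1D2, CLOCK, CXCL6, CCL5, UCP3, TG, the thyroid genes and the 2 most abundant identifiers were named after their values were seen. Some genes that the rule takes are not reported here.

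The count test and camera were tested on simulated counts for 18676 genes of this comparison, 3 libraries against 3. The simulated changes were placed only in genes with a mean over 1 CPM, so the recovery of lower genes was not measured. With dispersions as estimated, 10.4% of 2-fold, 67.2% of 4-fold and 89.4% of 8-fold changes were recovered, and 7 of 118 calls were false. Of 100 unshifted lists 4 had a camera p under 0.05, in counts simulated with a dispersion of 0.1 and with genes independent of each other. This rate does not carry over to lists whose members move together. In the real libraries 12 to 20 lists passed in every other split into 3 and 3. These splits keep part of a group difference, so this number is no rate of false calls.

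Alternatives were other size factors, other count filters, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, the replicate number as a block, and each library left out. After the data were seen, fits with only control replicate 1 kept, with smooth muscle or gland genes as a covariate, without the 2 most abundant identifiers, and with fry in either direction were added. File checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.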

Results

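RNA from tracheal tissue of rhesus monkeys was sequenced in 2 groups of 3 libraries. The control group received normal saline. The other group received a tracheal lubricant coated with a material called Oxy@Lipo/Gel, in an intubation model under general anaesthesia. The labels name the intubation model beside the Oxy@Lipo/Gel group and do not say whether the control animals were intubated. They call the replicates biosamples without stating that each is a separate animal, so the p-values measure the spread between these samples, part of which may be technical. Their tissue entry names a lubricated catheter for all 6 libraries, while the treatment text names tracheal tissue, and the extraction text speaks of cell lines. The control libraries held 22194965, 17097177 and 19592824 counts for replicates 1, 2 and 3. The Oxy@Lipo/Gel libraries held 21855604, 23405294 and 20089109 counts.

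The comparison of both groups asks how gene expression in the airway wall differs with a modified lubricated catheter, a question that the series raises to find targets linked to intubation injury. In the Oxy@Lipo/Gel libraries 5 of 17 submucosal gland genes, 6 of 25 B-cell and plasma-cell genes and 3 of 25 cartilage genes rose, among them LTF, MS4A1 and COL11A1. So did 4 of 20 complement and acute-phase genes, among them SAA1 and C3. Of 21 glucocorticoid-response genes 4 fell, such as FKBP5 and TSC22D3, and of 19 circadian clock genes 2 rose and 5 fell, with BMAL1 higher and TEF lower. None of these lists passed camera (a test of a whole gene list) with an estimated correlation (adjusted p from 0.478 to 0.569). Of 18676 genes tested with edgeR, 287 passed an adjusted p of 0.05, of which 159 were higher and 128 lower in the Oxy@Lipo/Gel group. All 287 had groups that did not overlap, as did 29.9% of all tested genes, where chance gives 10%. The 10% is an average over splits of the libraries, and the share in the other splits was not computed. Among the called genes 52 of the higher and 64 of the lower carry an identifier without a gene name. The count depended on single libraries: edgeR called 0 genes without control replicate 1, without control replicate 3 or without Oxy@Lipo/Gel replicate 2 (3189, 4858 and 2271 at an unadjusted p under 0.05), 20 without Oxy@Lipo/Gel replicate 3, 139 without control replicate 2 and 628 without Oxy@Lipo/Gel replicate 1. DESeq2 called 2492 genes on all 6 libraries, and these held all 287.

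Among the named genes with the largest rises, several encode secreted proteins of glands and mucosa. LTF, the iron-binding lactoferrin of gland secretions and neutrophil granules, rose from 11.6 ± 5.67 to 518 ± 392 CPM (normalised counts; mean ± SD, n = 3 in each group here and below), a log2 fold change of 5.47 ± 0.75 (SE; edgeR adjusted p = 0.0333). OLFM4, a secreted glycoprotein of mucosal epithelium and neutrophils, rose from 1.13 ± 0.687 to 57.5 ± 31.9 CPM (edgeR adjusted p = 0.0274). PRR4, a proline-rich protein of glandular secretions, rose from 0.785 ± 0.419 to 23.6 ± 13.5 CPM (edgeR adjusted p = 0.0274). DMBT1, a mucosal scavenger-receptor glycoprotein, rose from 214 ± 66.4 to 5963 ± 5495 CPM. Its edgeR adjusted p was 0.0496 and became 0.0513 with median-of-ratios size factors. CSN3, known as the milk protein kappa-casein, had 3 counts over the control group and 1242 over the Oxy@Lipo/Gel group, a ratio of 366 with a 95% interval of 125 to 1776. ODAM, an epithelial secreted protein, had 1 count against 439, a ratio of 388 with an interval of 69.3 to 15360. Both intervals are exact and cover counting error only, and the edgeR adjusted p was 0.0274 for CSN3 and 0.0409 for ODAM.

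Other large rises came from B-cell and acute-phase genes. MS4A1, which encodes the B-cell antigen CD20, rose by 5.56 ± 0.78 on the log2 scale (edgeR adjusted p = 0.0344). CXCL13, a chemokine that attracts B cells, rose from 0.387 ± 0.253 to 19.4 ± 12.4 CPM (edgeR adjusted p = 0.0411), and CLEC17A, a lectin of B cells, rose from 0.107 ± 0.0554 to 3.68 ± 1.77 CPM. The acute-phase gene SAA1 rose from 1.69 ± 0.454 to 58.3 ± 35.6 CPM and complement C3 from 5.97 ± 3.78 to 156 ± 43.8 CPM (edgeR adjusted p = 0.0257 for both). SAA1 and SAA2 are near-identical copies, so their split of the counts is uncertain. LRRN4 rose from 0.350 ± 0.225 to 9.81 ± 4.20 CPM.

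The largest falls included SERTM2, SULT1E1 and CYP2A24. SERTM2 had 293 counts over the control group and 0 over the Oxy@Lipo/Gel group, at least 110.5-fold lower against a floor of 3 counts over the group. SULT1E1, an oestrogen sulfotransferase, fell from 125 ± 104 to 1.94 ± 0.695 CPM (edgeR adjusted p = 0.0344). CYP2A24 fell from 12.3 ± 6.39 to 0.281 ± 0.0620 CPM, with the reservation that members of the CYP2A family share sequence. KLK4, a kallikrein protease, fell from 7.82 ± 6.37 to 0.129 ± 0.0770 CPM. HOPX, a homeodomain protein, was steady within groups and fell from 98.2 ± 7.92 to 17.5 ± 2.64 CPM (log2 fold change -2.49 ± 0.17, edgeR adjusted p = 0.0126). Further named falls were HPDL, DSCC1, CIART, TEF, ZBTB16 and VWC2, with log2 fold changes from -3.21 for HPDL to -2.21 for VWC2. With median-of-ratios size factors HPDL had an adjusted p of 0.0508.

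**Figure D1:**
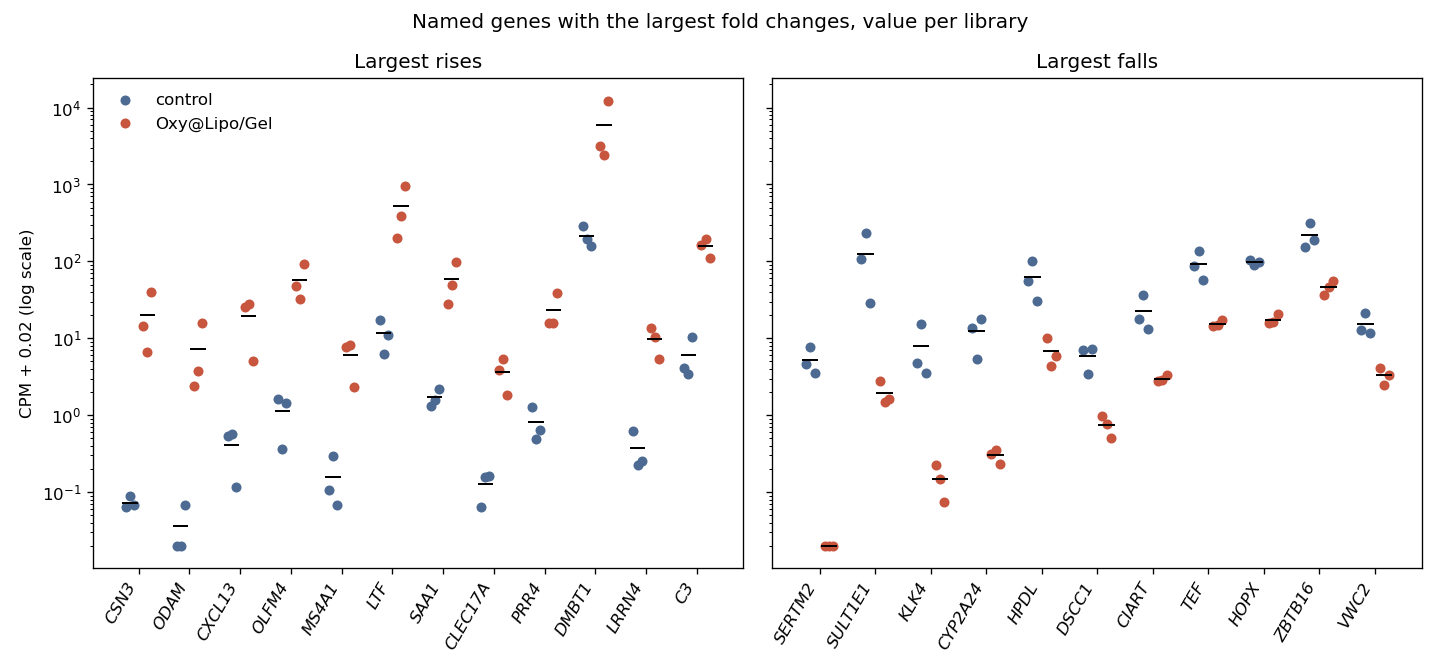
CPM plus 0.02 on a log axis for the genes named for the largest rises and falls and reported here, one point per library and a black line at the group mean of 3 libraries. The groups do not overlap for any of them, and SERTM2 has 0 counts in the 3 Oxy@Lipo/Gel libraries.

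Genes of glands, B cells and cartilage were in part higher in the Oxy@Lipo/Gel libraries. In the list of submucosal gland genes, 5 of 17 tested members rose (LTF, PRR4, DMBT1, ODAM and CA2), 0 fell and 12 did not pass, with 10 higher when adjusted over the list alone. The median log2 fold change was 2.54, and 1.53 without Oxy@Lipo/Gel replicate 3. CA2, carbonic anhydrase 2, rose from 0.731 ± 0.320 to 5.59 ± 2.47 CPM (edgeR adjusted p = 0.0479, and 0.0513 with median-of-ratios size factors). In the list of B and plasma cells 6 of 25 members rose and 0 fell, with 11 higher when adjusted over the list alone and a median of 1.73 (0.92 without Oxy@Lipo/Gel replicate 2). Among these were MS4A1, BLK, CD22, CD79A and CD79B. CD22, an inhibitory receptor of B cells, rose from 0.242 ± 0.0273 to 4.84 ± 2.21 CPM. In the chondrocyte list 3 of 25 members rose and 0 fell, with 10 higher when adjusted over the list alone and a median of 1.35. The cartilage collagen gene COL11A1 rose from 4.82 ± 2.10 to 44.1 ± 7.27 CPM, the link protein gene HAPLN1 from 0.953 ± 0.256 to 9.48 ± 3.70 and CNMD, which encodes chondromodulin, from 2.09 ± 0.453 to 17.8 ± 5.15. ACAN, the core protein of aggrecan, measured 8.17 ± 6.81 and 173 ± 95.4 CPM and did not pass (edgeR adjusted p = 0.0900). The gland, B-cell and chondrocyte lists passed camera with its preset correlation (adjusted p = 1.01e-09 for glands and 5.67e-10 for the others). With an estimated correlation the adjusted p was 0.499 for glands and 0.478 for B cells and for chondrocytes. For glands the camera p was as small in 2 of the 10 ways to split the 6 libraries into 3 and 3, the real split among them. For B cells and chondrocytes it was lowest in the real split. Without control replicate 2 the members higher numbered 0 for glands, 0 for B cells and 2 for chondrocytes. Without Oxy@Lipo/Gel replicate 3 they numbered 0, 4 and 0, and without Oxy@Lipo/Gel replicate 1 they numbered 5, 6 and 3. All 3 counts were 0 without control replicate 1, control replicate 3 or Oxy@Lipo/Gel replicate 2.

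Smooth muscle genes had a list median of 2.61 on the log2 scale, and 0 of 24 members passed over all genes, while 20 were higher when adjusted over the list alone. The list mean of Oxy@Lipo/Gel replicate 1 lay at -0.81 from the mean of all libraries, within the control range of -1.46 to -0.47, and replicates 2 and 3 lay at 1.72 and 2.14. MYOCD, the smooth muscle master regulator myocardin, measured 4.66 ± 0.343 and 42.3 ± 29.4 CPM (edgeR adjusted p = 0.0780). Without Oxy@Lipo/Gel replicate 1, 17 of the 24 members passed, and 0 without any other single library. KCNMB1, PDLIM3 and SYNM had log2 fold changes of 3.75, 3.01 and 3.06 and did not pass. The fibroblast list had a median of 0.87 (0.55 without Oxy@Lipo/Gel replicate 3) and 0 of 29 members passed, with COL3A1 at 62.8 ± 14.4 and 332 ± 213 CPM. In this list 10 members passed without Oxy@Lipo/Gel replicate 1, and 0 without any other single library. In the list of fibrillar collagens and crosslinking, which shares 8 genes with the fibroblast list, 1 of 27 members rose, with 8 higher and 2 lower when adjusted over the list alone. This was FN1, fibronectin, from 65.4 ± 5.91 to 401 ± 35.7 CPM (edgeR adjusted p = 0.0126). PLOD2 measured 12.9 ± 4.50 and 36.9 ± 5.13 CPM and did not pass. Without Oxy@Lipo/Gel replicate 1, 11 members of this list passed. The count was 1 without control replicate 2 or Oxy@Lipo/Gel replicate 3, and 0 without any other single library. The 3 lists passed camera with the preset correlation, and for each the adjusted p was 0.686 with an estimated correlation. For each, the camera p was as small in 4 of the 10 ways to split the 6 libraries into 3 and 3, the real split among them.

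**Figure D2:**
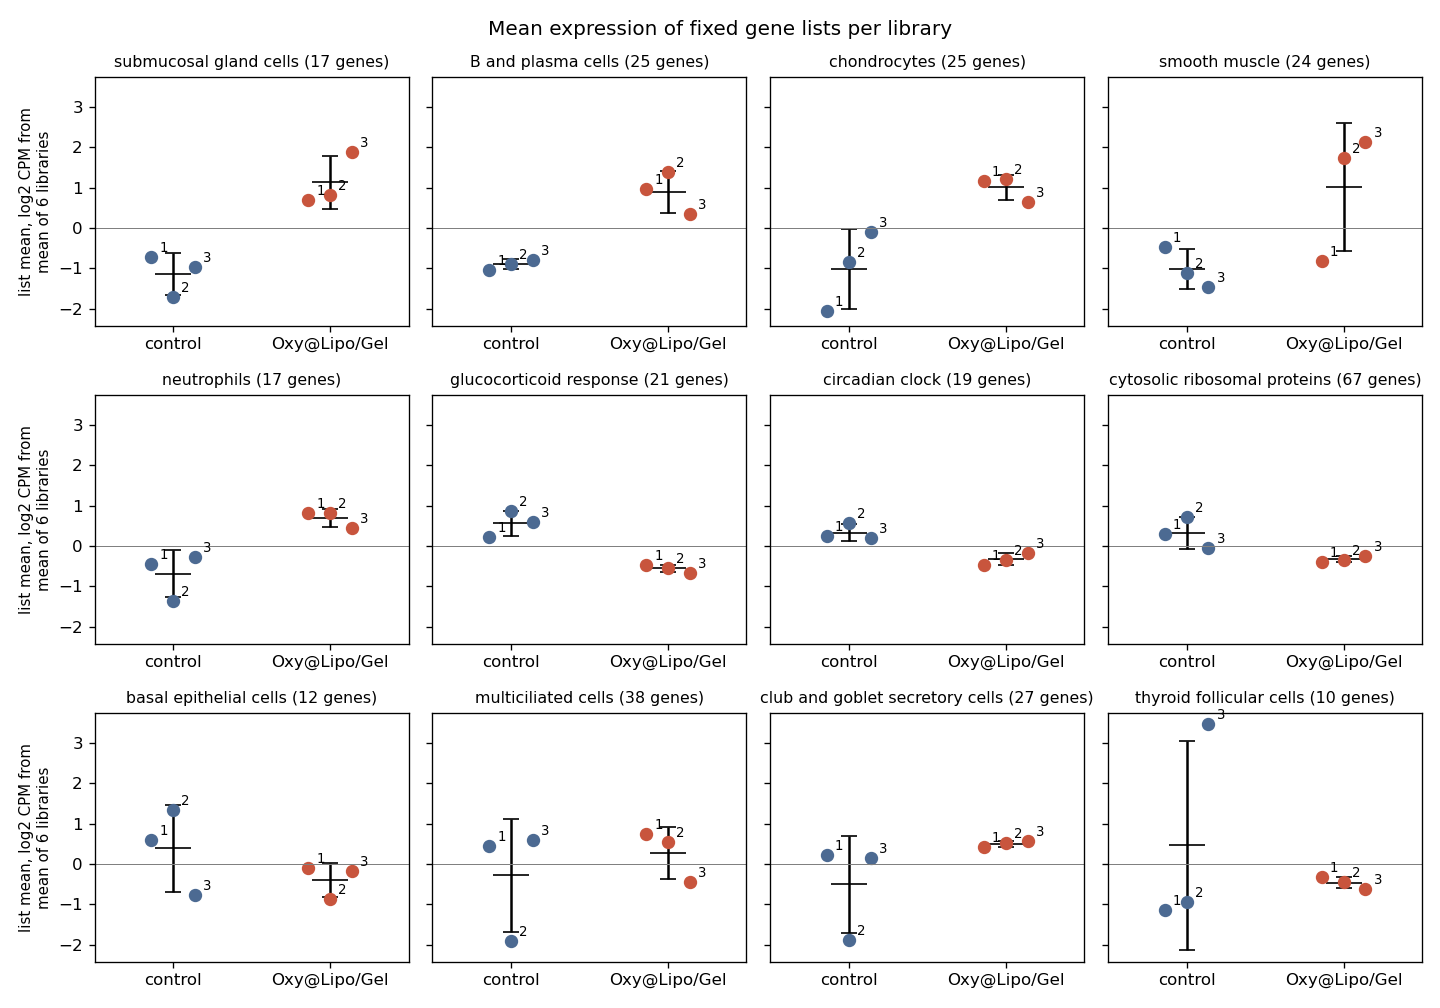
Mean log2 CPM of 12 fixed gene lists per library, relative to the mean of the 6 libraries. Numbered points are replicates, and black lines with bars are group means ± SD of 3 libraries. The glucocorticoid and clock lists separate the groups, as do the gland, B and plasma cell, chondrocyte, neutrophil, ribosomal protein and club and goblet lists. Oxy@Lipo/Gel replicate 1 lies at the control level for smooth muscle. Control replicate 2 lies at -1.90 for multiciliated cells and control replicate 3 at 3.45 for thyroid cells.

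Genes induced by glucocorticoids were in part lower. Of 21 tested members 4 fell, 0 rose and 17 did not pass, with 16 lower and 1 higher when adjusted over the list alone, and the median log2 fold change was -1.11. FKBP5, a co-chaperone of the glucocorticoid receptor, fell from 147 ± 22.5 to 44.7 ± 5.23 CPM (edgeR adjusted p = 0.0257). TSC22D3, the leucine zipper gene GILZ, fell from 300 ± 75.1 to 91.7 ± 6.75 CPM (edgeR adjusted p = 0.0325). ZBTB16 fell from 221 ± 84.8 to 46.2 ± 9.44 and ANGPTL4 from 28.9 ± 5.23 to 10.5 ± 2.15 CPM. The list passed camera with its preset correlation (adjusted p = 1.01e-11), and the adjusted p was 0.478 with an estimated correlation. The list mean of every Oxy@Lipo/Gel library lay below every control library, as the gland, B-cell and chondrocyte means lay above. In edgeR 4 members were lower without control replicate 2 and without Oxy@Lipo/Gel replicate 1, and 0 without any other single library.

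Some clock genes moved in opposite directions. BMAL1 and NPAS2, of the activating arm, rose from 10.2 ± 1.05 to 35.6 ± 6.75 CPM and from 19.5 ± 2.19 to 64.5 ± 14.5 CPM (edgeR adjusted p = 0.0257 and 0.0280). PER2, PER3, NR1D2, TEF and CIART, of the opposite arm, fell, PER2 from 102 ± 30.0 to 26.2 ± 5.15 CPM and CIART from 22.7 ± 12.4 to 2.96 ± 0.316 CPM (edgeR adjusted p = 0.0325 and 0.0344). CLOCK measured 26.8 ± 2.87 and 26.3 ± 1.75 CPM. In all, 2 of 19 members rose, 5 fell and 12 did not pass, with 2 higher and 9 lower when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.00112), and the adjusted p was 0.569 with an estimated correlation. The gland, B-cell and chondrocyte list means separated the same groups without overlap. The labels give a shared sampling day and no clock time. Without control replicate 2, 1 member was higher and 5 lower, without Oxy@Lipo/Gel replicate 1 2 were higher and 3 lower, and the count was 0 without any other single library.

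**Figure D3:**
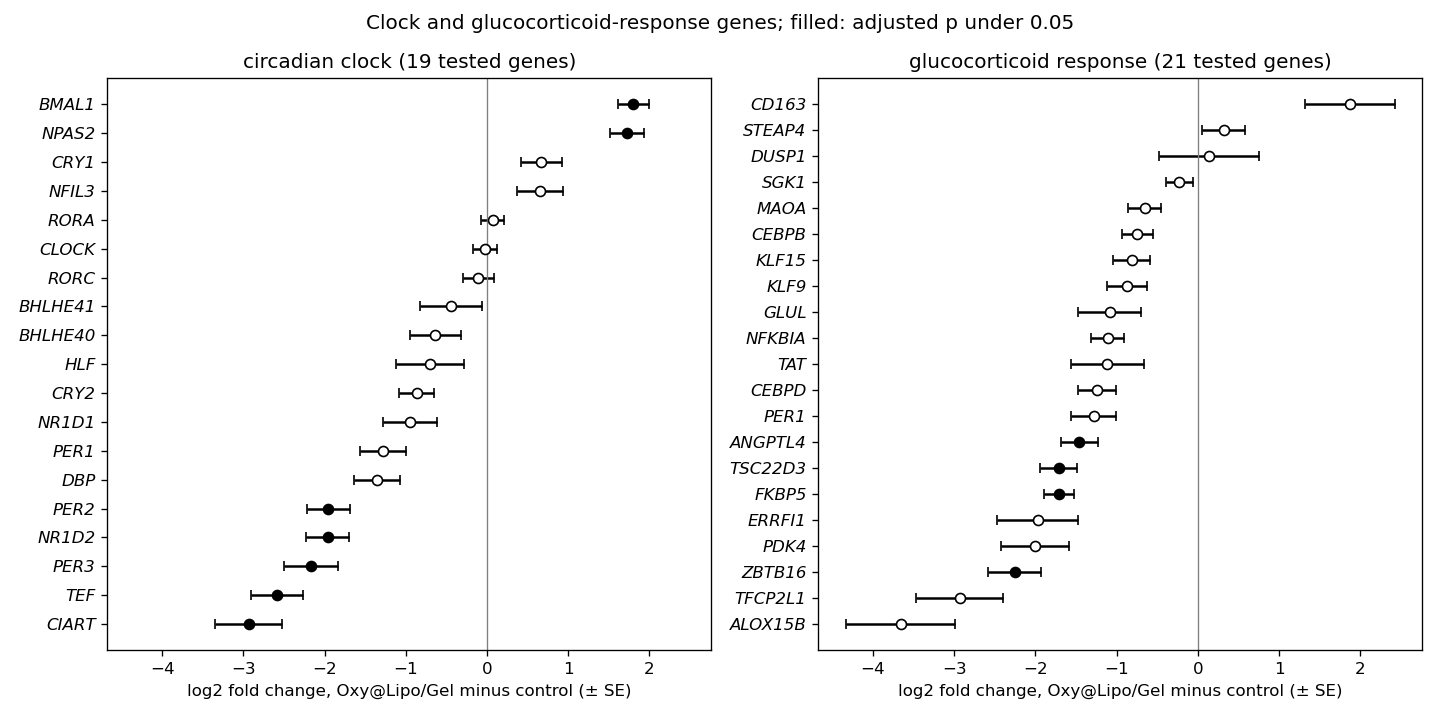
Log2 fold change ± SE, Oxy@Lipo/Gel minus control, of the 19 tested clock genes and the 21 tested glucocorticoid-response genes, with filled points for an edgeR adjusted p under 0.05. BMAL1 and NPAS2 lie at 1.80 and 1.73, and CIART at -2.93.

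Neutrophil, acute-phase and chemokine genes were in part higher. In the neutrophil list 3 of 17 members rose (MMP9, MPO and LTF) and 0 fell, with 8 higher when adjusted over the list alone. The protease gene MMP9 rose from 0.364 ± 0.0533 to 6.28 ± 1.96 CPM (edgeR adjusted p = 0.0229). MPO, myeloperoxidase, rose from 11.9 ± 1.47 to 63.5 ± 34.5 CPM (edgeR adjusted p = 0.0484, and 0.0513 with median-of-ratios size factors). LTF is also a gland gene, and the gland list mean separated the groups. In the list of complement and acute phase 4 of 20 members rose (SAA1, C3, SAA2 and SERPINA3) and 0 fell, with 5 higher and 1 lower when adjusted over the list alone. Its log2 fold changes were above 0 for 15 members and below 0 for 5, with a median of 0.56. This median was 0.22 without Oxy@Lipo/Gel replicate 3 and 1.02 without control replicate 3, the lowest and highest with a library left out. SERPINA3, an acute-phase protease inhibitor, rose from 99.6 ± 39.6 to 1278 ± 704 CPM. The neutrophil and acute-phase lists passed camera with the preset correlation, and for both the adjusted p was 0.478 with an estimated correlation. The list of proinflammatory cytokines and chemokines did not pass (adjusted p = 0.232), and 2 of its 15 tested members rose and 1 fell, the same when adjusted over the list alone. CXCL1, a neutrophil chemokine, rose from 3.43 ± 0.405 to 36.7 ± 15.9 CPM (edgeR adjusted p = 0.0257), CXCL6 rose and CCL5 fell. Without control replicate 2, 1 neutrophil and 1 acute-phase member passed. Without Oxy@Lipo/Gel replicate 3 each count was 1, without Oxy@Lipo/Gel replicate 1 they were 2 and 4, and without any other single library 0.

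Of 67 ribosomal protein genes 0 passed in edgeR, also when adjusted over the list alone. All 67 log2 fold changes were below 0 and their median was -0.68, and -0.46 without control replicate 2. The list mean of control replicate 2 was 0.72, against 0.31 and -0.06 in control replicates 1 and 3 and -0.39 to -0.24 in the Oxy@Lipo/Gel libraries. The list passed camera with the preset correlation (adjusted p = 1.56e-13) and had an adjusted p of 0.686 with an estimated correlation. Its camera p was as small in 3 of the 10 ways to split the 6 libraries into 3 and 3, the real split among them. RPS27 measured 632 ± 230 and 274 ± 14.5 CPM (edgeR adjusted p = 0.104), RPL31 567 ± 106 and 323 ± 29.9, RPS21 399 ± 118 and 211 ± 25.8, and RPL11 741 ± 212 and 385 ± 22.7. Such genes have many processed pseudogenes, so their counts are uncertain.

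Epithelial lists moved with single libraries. The multiciliated list (median 0.21, 0 of 38 members past the test) and the list of club and goblet secretory cells (median 0.51) passed camera with the preset correlation, with an adjusted p of 0.846 and 0.686 with an estimated correlation. Control replicate 2 lay at -1.90 and -1.89 in these lists, the other control libraries between 0.15 and 0.60. Without control replicate 2 neither list passed (adjusted p = 0.193 and 0.215), and the medians were -0.25 and 0.37. Without control replicate 3 the medians were 0.64 and 0.95, and without control replicate 1 they were 0.46 and 1.00. They were -0.02 and 0.52 without Oxy@Lipo/Gel replicate 1, and 0.53 and 0.46 without Oxy@Lipo/Gel replicate 3. The multiciliated list also did not pass without Oxy@Lipo/Gel replicate 1 or 2 (adjusted p = 0.674 and 0.176). BPIFB1, an antimicrobial secretory protein of the airway, rose from 116 ± 62.5 to 1318 ± 195 CPM (edgeR adjusted p = 0.0383). The basal-cell list had a median of -1.08 and 0 of 12 members passed, with TP63 at 236 ± 164 and 77.9 ± 38.6 CPM. The desmosome list had a median of -0.65 and 0 of 18 members passed, with PKP2 at 36.4 ± 11.7 and 16.2 ± 2.40 CPM. Both passed camera with the preset correlation, but not without control replicate 2 (medians -0.64 and -0.41, adjusted p = 0.209 and 0.125), and had an adjusted p of 0.686 with an estimated correlation. Control replicate 2 also had 23.99% of its counts in 2 identifiers without a gene name, LOC123573629 and LOC123573628, against 9.63% to 12.8% in the other 5 libraries. The thyroid list mean of control replicate 3 was 3.45, and TG, thyroglobulin, had 98772 counts there and 98 to 149 in the other libraries.

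Genes tied to pain and mucosal injury were in the main not past the test. SCN9A, a sodium channel of sensory neurons, measured 3.96 ± 1.25 and 1.57 ± 0.567 CPM (edgeR adjusted p = 0.138). TRPV1, the capsaicin receptor, measured 7.47 ± 0.794 and 3.77 ± 1.23 CPM (edgeR adjusted p = 0.137). PTGS2, the inducible cyclooxygenase, measured 4.84 ± 4.29 and 2.93 ± 0.608 CPM, and IL6 measured 4.01 ± 3.65 and 1.99 ± 0.672 CPM. TNF measured 0.697 ± 0.880 and 0.734 ± 0.421, and CXCL8 measured 2.07 ± 1.12 and 6.03 ± 2.30 CPM (edgeR adjusted p = 0.157). SCN10A, IL1B, CALCA and TAC1 stayed under the count filter, with at most 4, 21, 1 and 29 counts in a library. TRPM8, the cold and menthol receptor, fell from 1.68 ± 0.0931 to 0.354 ± 0.126 CPM (edgeR adjusted p = 0.0433). The lists of nociceptor genes and of sodium channels did not pass camera (adjusted p = 0.832 and 0.802). Of 23 nociceptor members 1 fell and 0 rose, with 2 higher and 3 lower when adjusted over the list alone, and fry in either direction gave an adjusted p of 0.00105. Of 10 sodium channel members 0 passed, also over the list alone (fry 0.0874).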

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

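Against 287 genes in the main edgeR test, median-of-ratios size factors gave 269 genes (263 shared), no filter 313 (262), a filter at 1 CPM 267 (263), a fold threshold 272 (272) and limma-voom 199 (195). No scaling gave 183, DESeq2 2492, and limma-trend on deposited FPKM gave 139 with a pseudocount of 1, 135 with 0.1 and 125 without a filter. Leaving out each library gave 0 to 628 genes, with the share of higher calls at 39.6% without control replicate 2 and 83.0% without Oxy@Lipo/Gel replicate 1, against 55.4% with all. In alternatives chosen after seeing the data, edgeR gave 0 genes with only control replicate 1 kept, 0 with a smooth muscle covariate and 0 with a gland covariate (2951, 2025 and 554 at an unadjusted p under 0.05), and 281 without the 2 most abundant identifiers. A covariate or a missing library also leaves fewer degrees of freedom. The gland list mean correlates with the group at 0.9195 and the smooth muscle list mean at 0.726, and both hold genes under test. With such overlap, calls can be lost and directions can turn whatever the cause. The covariate fits therefore cannot decide whether tissue shares account for the calls. Of 43 lists, 19 passed camera with the preset correlation, 0 with an estimated correlation (4 unadjusted, lowest adjusted p = 0.478) and 0 with directional fry (10 unadjusted, lowest adjusted p = 0.0958). Leaving out each library gave 17 to 22 lists, and fry in either direction, chosen after seeing the data, gave 22, of which 11 were among the 19. It ended the call of 8 lists (such as smooth muscle, ribosomal protein and fibroblast lists) and added 11 (such as nociceptor and fatty acid lists). The multiciliated list turned lower without control replicate 2, over an adjusted p of 0.000709 to 0.674 with each library left out, and with only control replicate 1 kept (adjusted p = 0.484). With the gland covariate the direction turned for multiciliated (adjusted p = 0.575), club and goblet (0.00031), macrophage (0.17), fibroblast (0.239), smooth muscle (0.576) and Schwann cell lists (4.25e-05), and with the smooth muscle covariate for fibroblasts (0.114). The cause was not tested. Listed genes past the test when adjusted over the list alone numbered 140, with 143 under median-of-ratios factors and 81 to 216 with each library left out. In these numbers a gene held by several lists is counted in each list where it passed. Genes named by the fixed rule were retested with median-of-ratios factors, DESeq2, log2(FPKM + 1) where tested, the replicate block, each library left out, only control replicate 1 kept and both covariates. None of the 44 called changed direction. All 44 lost their call with the replicate block, without control replicate 1 or 3, without Oxy@Lipo/Gel replicate 2, with only control replicate 1 kept and with each covariate. The call was lost by 35 without Oxy@Lipo/Gel replicate 3, 23 without control replicate 2, 4 without Oxy@Lipo/Gel replicate 1, 4 with median-of-ratios factors, 14 with log2(FPKM + 1) and 0 with DESeq2. Without scaling 10 lost it (ANGPTL4, BPIFB1, CA2, CLDN10, CXCL13, DMBT1, DSCC1, HPDL, MPO and TRPM8). Replicate numbers 1, 2 and 3 occur in both groups, and deviations of same-numbered samples correlated at 0.24, -0.39 and -0.21. Control replicate 1 correlated best with its own number, and control replicates 2 and 3 with another number. These values show no pairing by number but cannot exclude one, because deviations from a mean of 3 libraries depend on each other. With the replicate block, edgeR gave 0 genes (2866 unadjusted), 89 listed genes and 22 lists. The 4 markers under the count filter were not tested, and 2-fold changes were recovered in 10.4% of simulated cases, all at a mean over 1 CPM.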

Other observations

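Lists not described so far gave mixed results. The lists of macrophages and monocytes (median log2 fold change 0.56), cell cycle (0.47), extracellular matrix proteases (0.24) and NRF2 targets (-0.44) passed camera with the preset correlation, each with an adjusted p of 0.686 with an estimated correlation. With each library left out the macrophage median ranged from 0.37 to 0.92 and the protease median reached 0.69. Single libraries ended 3 of these calls: cell cycle without control replicate 3 or Oxy@Lipo/Gel replicate 1 (adjusted p = 0.132 and 0.213), proteases without control replicate 1 (0.0693), and NRF2 targets without control replicate 3 or Oxy@Lipo/Gel replicate 3 (0.146 and 0.117). LYZ, lysozyme, measured 594 ± 323 and 10079 ± 5165 CPM (edgeR adjusted p = 0.0525), and it is also a gland gene. RRM2 of the cell cycle list measured 7.01 ± 3.04 and 19.1 ± 6.39 CPM, and OSGIN1 of the NRF2 list 56.0 ± 27.3 and 13.1 ± 1.92 CPM (edgeR adjusted p = 0.0501). MMP9 of the protease list rose, and adjusted over the list alone 5 members were higher and 1 lower. In the list of tight and adherens junctions, which did not pass (adjusted p = 0.95), CLDN10 rose from 0.939 ± 0.227 to 4.28 ± 1.2 CPM. In the fatty acid list, whose median is 0.10 and mean -0.16 (adjusted p = 0.406), UCP3 fell.

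With all 6 libraries the remaining lists did not pass camera with the preset correlation. Cell types among them were Schwann cells and neurons (adjusted p = 0.126), alveolar epithelium (0.147), endothelium (0.193), eosinophils (0.238), skeletal muscle (0.385), thyroid cells (0.387), T and NK cells (0.406), mast cells (0.549), adipocytes (0.823) and squamous epithelium (0.926). HOPX, named among the falls, is the member of the alveolar list that fell. Responses among them were oxidative phosphorylation (0.136), type I interferon (0.153), hypoxia and glycolysis (0.258), in which ANGPTL4 fell, and prostaglandin synthesis (0.406), with ALOX15B at 18.9 ± 13.6 and 1.48 ± 0.863 CPM. The unfolded protein, apoptosis, cholesterol and immediate early lists each had an adjusted p of 0.300, and NF-kB regulators one of 0.440. Some passed with a library left out: adipocytes (median 1.84) and Schwann cells (1.46) without control replicate 3, Schwann cells (0.49) also without Oxy@Lipo/Gel replicate 1, endothelium (-0.56) and thyroid cells (-3.05) without control replicate 1, and immediate early genes (0.48) and oxidative phosphorylation (-0.24) without control replicate 2. Endothelium also passed without Oxy@Lipo/Gel replicate 2 or 3 (-0.49 and -0.66), and T and NK cells (0.56), alveolar epithelium (1.2) and type I interferon (-0.35) without Oxy@Lipo/Gel replicate 3. Adjusted over the list alone, members higher and lower numbered 1 and 5 in the fatty acid list, 2 and 1 for NF-kB regulators, 2 and 0 for eosinophils, 1 and 1 for alveolar epithelium, and at most 1 member in each of the other lists named above in this paragraph. Median and mean differ in sign for mast cells (-0.36 and 0.01), adipocytes (0.12 and -0.03) and nociceptor genes (0.12 and -0.06).

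The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 287 genes and the highest other 0 (1 of 10 splits with as many). It gave 19 lists and the highest other 20 (2 of 10), and 140 listed genes, counted once per list, against 101 (1 of 10). Lists passed camera in every other split, 12 to 20 of them. Each of these splits mixes the groups unequally and so keeps part of a group difference. The passing lists can stem from that part or from a structure of the samples that the preset correlation does not take up. Their number does not tell these apart. Of 43 lists 6 had their lowest camera p in the real split, where chance gives 4.3. These were glucocorticoid response, circadian clock, chondrocytes, B and plasma cells, neutrophils, and complement and acute phase.

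Of the tests that follow, those of the tissue shares, the clock phase, the thyroid tissue and the mislabelled piece were chosen after the results were seen. Gland, B-cell and cartilage genes were in part higher in the Oxy@Lipo/Gel libraries, and smooth muscle genes in 2 of the 3. A lower share of one main cell type would raise every other type alike. The gland minus endothelial list mean differed between the groups by 2.67 on the log2 scale (within-group SD 0.702), with no overlap. This pair was picked after both list means were seen. The value therefore restates that endothelial genes did not rise with gland genes, and is no separate test of this explanation. Within groups, the members of 4 of 4 lists moved together more than 95% of 1000 random lists, which the estimated correlations had already shown and which a joint response would give as well. Unequal tissue shares and a response to the coated lubricant cannot be told apart, because the share of each tissue in the pieces was not measured. Intubation itself cannot be told apart from the lubricant either, because the labels do not say whether the control animals were intubated.

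Of 21 glucocorticoid-response genes 4 fell, and of 19 clock genes 2 rose and 5 fell, with list adjusted p of 0.478 and 0.569 with an estimated correlation. With the smooth muscle list as a covariate the group difference of the glucocorticoid list mean was -0.9456 ± 0.285 (SE), against -1.11 ± 0.188 without it. The difference kept its sign at -3.316 SE, only just past the 95% bound of 3.182 with 3 degrees of freedom. The smooth muscle mean correlates with the group at 0.726 and only stands in for an unmeasured tissue share. An unequal share of smooth muscle is therefore not excluded. With the gland list as a covariate it was -0.432 ± 0.347, and the gland share and the group cannot be told apart here, because the gland mean correlates with the group at 0.9195. The BMAL1 arm minus the opposite arm of the clock differed by 2.56 (within-group SD 0.340) with no overlap, but the arms hold the called genes and leave out other clock genes, so this value restates the calls. Clock phase and group cannot be told apart, because the labels give no clock time. Glucocorticoid exposure during anaesthesia, intubation itself and a response to the material stay open and untested.

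Control replicate 3 had 692 times the TG level of the highest other library. Of 10 tested thyroid genes, 5 were at least 4-fold higher there than in any other library (among them TG, PAX8, DIO1 and HHEX), with PAX8 at 168 CPM against 1.43. The multiciliated list mean of this library was 0.597, above the median of 0.453 of the other libraries, so it did not lack genes of ciliated cells. This mean was seen before the test was chosen, and the lowest library was control replicate 2 at -1.90. The test therefore cannot decide whether a piece was mislabelled. Thyroid tissue in the piece is a candidate source, and the design names no biological difference for this library to test.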
